A study of Mus musculus with 122 samples.

How the data were processed

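The series measured messenger RNA bound to tagged ribosomes in 7 types of mouse neuron by the bacTRAP method: a transgene on a bacterial artificial chromosome puts a green fluorescent ribosomal protein, eGFP-L10a, into the cells that use the chosen driver gene, and polysomes are pulled down through the tag before sequencing. Per the labels, each of the 122 libraries came from a pool of 2 mice, 5 ng of immunoprecipitated RNA was amplified, and the wild-type mice were male. Neurons of layer II of the entorhinal cortex (ECII) were tagged with 4 lines, a pair with BACs of Rasgrp2 and a pair of founders with a BAC of Sh3bgrl2. Pyramidal cells of hippocampal field CA1 were tagged with 2 lines, Sstr4 and Cck. The other types had 1 line each: Cacng5 for CA2, Gprin3 for CA3, another founder of the Sstr4 BAC for dentate gyrus granule cells (DG), Cartpt for primary somatosensory cortex (S1) and Calca for primary visual cortex (V1).

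The deposited values are raw counts of reads per gene, 1 table per library, which the authors made with STAR 2.3.0e and HTSeq 0.9.1 per the submitters' processing notes. The genome build, the annotation release and the strand setting are not given in the sources used here, so genes that overlap or share an antisense partner, and close paralogs, are reported as uncertain. The tables hold 39179 Ensembl mouse genes, of which 37607 were given a symbol from the reference annotation and 1572 were not. Reads assigned to genes numbered from 2.792 to 47.47 M (mega) per library, with a median of 31.251 M. Beside these, the deposited tables list reads in no annotated gene, 7.32 to 14.69% of the listed reads, ambiguous reads, 0.82 to 1.72%, and reads that aligned to several places, 10.51 to 31.01%. The values were checked to be whole numbers. Replicates varied by more than counting error: over the 431 pairs of libraries of a group, the smallest chi-square per gene was 5.92, where counting error alone gives about 1. The standard errors of log2 changes and the SDs of means include this spread between libraries. Those given over the members of a gene list are a spread between genes.

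Libraries were grouped by neuron type and age from the labels into 22 groups. The library names carry running numbers that fall into 4 blocks for the wild-type libraries, here called number runs A to D, and the APP/PS1 set has its own numbering. The labels do not say what the numbers stand for. All 24-month libraries have numbers of run C, all 12-month libraries have numbers of run B, and the 4-5-month libraries are spread over runs A, B and D, except 3 of CA2 in run C.

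Tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's filterByExpr (a minimum count of 10 and a total of 15) and its quasi-likelihood F test, with Benjamini-Hochberg adjustment within a comparison. Identity comparisons set 1 type against the unweighted mean of the log expression of the 6 others at 4-5 months, in a single fit of 50 libraries. Age comparisons were fitted within a type, with the line as a covariate where a type had several. APP/PS1 libraries were fitted with sex as a covariate. Lines of 1 type were compared at 4-5 months, and the age change of ECII neurons was compared with that of the 5 other types with 24-month libraries in a fit with a mean per line and age. Identity and line comparisons called genes at an adjusted p under 0.05 and a fold of at least 2, and all other comparisons at an adjusted p under 0.05. The ± after a log2 change is its standard error, and the ± after a mean is the SD between libraries; CPM are counts per M assigned reads with TMM scaling.

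The 35 gene lists tested (markers of neuron types and of other cell types, pathways and complexes), the groups, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 3 tested members were tested by camera of limma 3.58.1, with an inter-gene correlation of 0.01 and adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Called members were counted over all genes tested and also adjusted over the list alone. Named genes are those called with a symbol of their own and a mean of at least 5 CPM: the 10 with the largest change each way for ECII identity, ECII with CA1, ECII at 24 months and APP/PS1; 5 for the other identities and each way for the difference in age change; and 3 each way for the others. The driver genes, Ptbp1, App, Prnp, Thy1, 5 sex genes and the 4 called members of a list with the smallest adjusted p could also be named. Some genes that this rule names are withheld, and their results are left out of the text.

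Alternatives were DESeq2's size factors and library size alone in place of TMM, no filter, a filter at 5 CPM, DESeq2 1.42.0, limma-voom with the line as a block, a mean per line, the number run as a covariate or run B alone, each line or library left out, and fold minimums. After the data had been seen, further alternatives were added, among them the ECII comparisons without the Rasgrp2 lines. The pipeline was tested on simulated counts, drawn from a single mean per gene, a dispersion trend and the sizes of the real libraries. With 200 genes changed 1.5-, 2- or 4-fold in a group, the test recovered 79.1% of the 2-fold changes in the ECII design at 24 months. It recovered 44.8% in the DG design at 24 months, 17.9% in the S1 design at 12 months and 3% in the APP/PS1 design. The simulated counts held no differences between lines or number runs and no spread particular to a gene. Recovery in the real libraries may therefore differ. Figures were drawn with matplotlib 3.10.9, and the tables were read with pandas 2.3.3. Raw reads, splicing and expression in human tissue were not analysed here.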

Results

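Messenger RNA bound to tagged ribosomes was sequenced from 122 libraries, 111 of wild-type mice and 11 of the APP/PS1 set. At 4-5 months there were 17 libraries of ECII neurons, 9 each of CA1 and CA2, 6 of S1 and 3 each of DG, CA3 and V1. At 12 months there were 10 of ECII, 6 of CA1 and 3 each of CA2, CA3, DG, S1 and V1. At 24 months there were 12 of ECII, 6 of CA1 and 3 each of CA3, DG, S1 and V1, and none of CA2. The APP/PS1 set, ECII neurons at 6 months, had 8 libraries of mice with the APP/PS1 transgenes (4 of females and 4 of males) and 3 without them (2 of males and 1 of females). Depth differed between groups. The median library held 32.173 M assigned reads (M, mega) in ECII at 4-5 months (range 2.792 to 44.07) and 16.072 M in DG (10.646 to 16.385). It held 35.614 M in DG at 24 months (32.955 to 40.164). In the APP/PS1 set the medians were 20.8 M with the transgenes (9.902 to 35.829) and 11.383 M without (7.202 to 22.001), and the libraries without them detected 12514 to 16073 genes against 14846 to 17891.

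The genes whose BACs marked the cells were compared between types, to ask whether the tagged cells express the gene that drives the tag. Sh3bgrl2 averaged 165 ± 91 CPM in ECII (n = 17) and 28.2 ± 9.08 in the other types (n = 33), and Rasgrp2 27.5 ± 19.3 against 3.08 ± 2.43. Cacng5 averaged 186 ± 70.5 CPM in CA2 (n = 9) and 23.8 ± 23.4 in the others (n = 41). Gprin3 averaged 34.9 ± 8.49 CPM in CA3 (n = 3) against 6.17 ± 3.39, Cartpt 42.9 ± 23.4 in S1 (n = 6) against 2.22 ± 1.6, and Calca 9.63 ± 3.04 in V1 (n = 3) against 0.446 ± 0.427. Each was called higher in its own type, by log2 differences of 2.68 ± 0.19 for Sh3bgrl2, 3.56 ± 0.32 for Rasgrp2, 4.37 ± 0.33 for Cacng5, 2.67 ± 0.26 for Gprin3, 4.60 ± 0.41 for Cartpt and 5.57 ± 0.60 for Calca. The Cck gene, whose BAC marked CA1 in another line, did not follow this: Cck averaged 834 ± 114 CPM in that line (n = 6), 1080 ± 199 in the Sstr4 line of CA1 (n = 3) and 1740 ± 289 in CA3 (n = 3). In CA1 against the other types Cck differed by 0.74, below the fold of 2 needed for a call. The Sstr4 BAC marked CA1 in one founder and DG in another. Sstr4 was higher in CA1, at 58.4 ± 14.4 CPM (n = 9) against 15.1 ± 8.19, and was not called in DG, at 17.6 ± 3.42 (n = 3). A BAC may carry a copy of its own gene, so these differences are not independent of the transgene. Cartpt ran from 5.59 to 64.9 CPM in the 6 S1 libraries. Its lowest value there lay within the 0.982 to 7.47 CPM of Sh3bgrl2 founder #26 in ECII.

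ECII neurons were compared with the 6 other types at 4-5 months to find what sets apart the cells that are among the first lost in Alzheimer's disease. Reln, the secreted protein that marks many layer II entorhinal neurons, was higher by 4.69 ± 0.22 on the log2 scale (489 ± 178 CPM, n = 17), and the Wnt transcription factor gene Lef1 by 4.27. Hpca, a calcium sensor abundant in hippocampal pyramidal cells, fell by 2.62 on the log2 scale (± 0.16), with 487 ± 178 CPM against 4950 ± 3440. The homeobox gene Emx2 was lower by log2 -2.85 ± 0.25, as were the calcium-binding copine Cpne9 (-3.15), Ccbe1 (-3.24) and the lactase gene Lct (-3.64). Among the 10 genes with the largest differences upward, Acta2, the actin of vascular smooth muscle, was at 671 ± 1270 CPM against 2.02 ± 2.08 (log2 8.80 ± 0.95), and Myl9 at 525 ± 892 against 2.31 ± 1.77. The others were Actg2, Map3k7cl, Foxs1, Pln, Higd1b, Aspn, Il2ra and Myocd. Of 15 endothelial and mural markers 14 were higher (14 adjusted over the list alone, median 3.24, camera adjusted p = 0.917 with an estimated correlation). By edgeR's quasi-likelihood test, 2781 genes were called higher and 515 lower of 18778, 3296 in all, where limma-voom with the line as a block called 1652. That method also called fewer for the other types than edgeR, 1233 for CA1, 1376 for CA2, 1236 for CA3, 679 for DG, 1516 for S1 and 2091 for V1. The ECII markers had 6 of 8 members higher, and 6 adjusted over the list alone (camera adjusted p = 1.33e-07 with an estimated correlation), and 13 of 16 oligodendrocyte markers were lower (13 adjusted over the list alone, camera adjusted p = 0.00948 with an estimated correlation). Cholesterol synthesis genes had a median log2 difference of 0.57, with 4 of 23 higher (4 adjusted over the list alone), and camera's adjusted p rose from 8.32e-08 to 0.0707 with an estimated correlation. The median over all genes was 0.11 with TMM scaling and 0.21 with library size only.

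Smooth muscle genes differed between the ECII lines. In the 6 libraries of the Rasgrp2 lines Actg2 averaged 37.5 ± 27 CPM and in the 11 of the Sh3bgrl2 founders 0.00278 ± 0.00921, and Aoc3 30.1 ± 21.8 against 0.00247 ± 0.00819. The pericyte genes Vtn, Rgs5, Abcc9 and Kcnj8 were higher in the Rasgrp2 lines by log2 8.09, 7.97, 8.99 and 9.72. Cldn5, a tight junction gene of endothelial cells, averaged 8.24 ± 1.04 and 10.4 ± 4.92 CPM in the Rasgrp2 lines (n = 3 each) and 0.508 ± 0.223 (n = 5) and 0.0384 ± 0.0659 (n = 6) in the Sh3bgrl2 founders. Fam216b (log2 -5.95 ± 1.17), Dynlrb2 (-5.39 ± 1.03) and Ccdc153 (-4.47 ± 0.97) were lower in the Rasgrp2 lines. Between the lines 2361 genes were called higher and 399 lower of 17445. All 15 endothelial and mural markers tested were higher (15 adjusted over the list alone), with a median of 5.36 (camera adjusted p = 3.09e-05 with an estimated correlation). Oligodendrocyte markers had 13 of 16 higher (14 adjusted over the list alone, median 1.90, camera adjusted p = 0.0435 with an estimated correlation). Microglia markers had 12 of 18 (13 adjusted over the list alone), median 1.60, and astrocyte markers 7 of 15 (7 adjusted over the list alone), median 0.98. Interferon and MHC class I genes had 21 of 30 (21 adjusted over the list alone), median 2.50. Camera's adjusted p with an estimated correlation was 0.228, 0.228 and 0.107 for these 3 lists. Within number run A alone, 3 Rasgrp2 against 5 Sh3bgrl2 libraries, 3391 genes were called and the median of the endothelial and mural markers was 6.15.

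Ptbp1, which encodes a splicing repressor that neurons turn down as they mature, differed between the ECII lines. It averaged 83.2 ± 35 and 110 ± 24.2 CPM in the Rasgrp2 lines (n = 3 each), and 34.6 ± 13.5 (n = 5) and 16.5 ± 4.71 (n = 6) in Sh3bgrl2 founders #26 and #33. The other types fell between 6.48 ± 1.84 CPM in CA3 (n = 3) and 34.1 ± 9.82 in S1 (n = 6). Ptbp1 was higher in ECII than in the other types by 1.37 ± 0.24 on the log2 scale with all 4 lines (edgeR's quasi-likelihood test, adjusted p = 8.74e-06; 11 of 17 libraries above the mean of the other types), and by 0.36 ± 0.20 in the 11 Sh3bgrl2 libraries alone (edgeR's test, adjusted p = 0.153). Between the Rasgrp2 and the Sh3bgrl2 lines the difference was 2.02 ± 0.20 (edgeR's test, adjusted p = 1.32e-07; 6 of 6 Rasgrp2 libraries above the Sh3bgrl2 mean). Without the Rasgrp2 lines 2453 genes were called for ECII. Reln was then higher by 4.76 ± 0.23 and Sh3bgrl2 by 3.10, the thyrotropin-releasing hormone gene Trh by 6.70 ± 0.73 and Dcn, which encodes the matrix protein decorin, by 5.54 ± 0.26 (132 ± 41.7 CPM, n = 11, against 7.16 ± 8.3). Ccdc153, Fam216b and Dynlrb2 were also among the 10 genes with the largest differences upward, by 6.265, 5.519 and 4.764. They varied widely between the 11 libraries, at 18.1 ± 14, 8.15 ± 7.3 and 11.3 ± 11.9 CPM. Whether they come from other cells was not tested. The myelin gene Mog was lower by log2 -4.40.

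**Figure D1:**
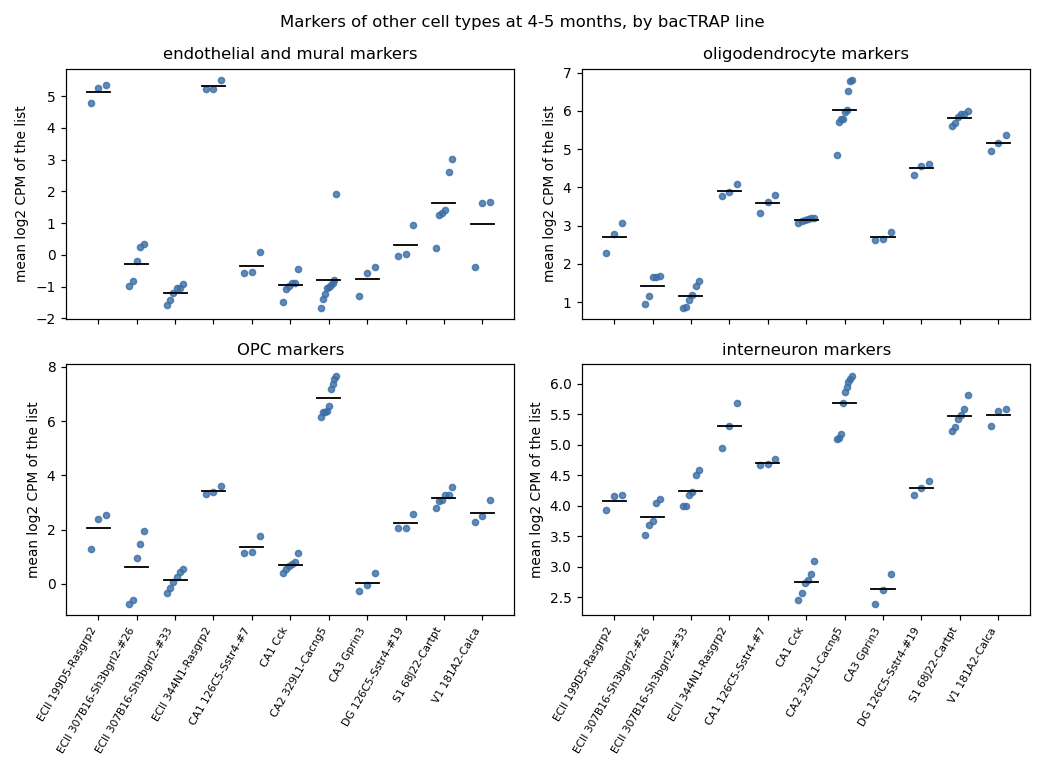
Mean log2 CPM of the marker lists of endothelial and mural cells, oligodendrocytes, oligodendrocyte precursors and interneurons in each library at 4-5 months, by transgenic line; each point is 1 library and each bar the mean of a line. The 6 libraries of the Rasgrp2 lines stand apart for endothelial and mural markers, and the 9 of the Cacng5 line, which marks CA2, for oligodendrocyte precursor markers.

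CA1 pyramidal cells were compared in the same way, as the hippocampal field that degenerates early. Fibcd1, an established CA1 marker, was at 137 ± 17.9 CPM (n = 9) against 10.1 ± 7.39 (n = 41), a log2 difference of 5.02 ± 0.30. Lefty1, a secreted inhibitor of Nodal, was higher by 5.58 ± 0.48, Lct by 4.54, the protease inhibitor Spink8 by 4.05 and Klk8 by 4.49, though kallikreins can share reads with their paralogs. Synaptic release genes were low as a group, with a median of -0.56 (7 of 42 lower, 7 adjusted over the list alone, camera adjusted p = 0.0179 with an estimated correlation). By edgeR's test 792 genes were called higher and 1754 lower, and all 9 CA1 markers were higher (9 adjusted over the list alone, median 2.96, camera adjusted p = 3.17e-10 with an estimated correlation). Proteasome genes had a median of 0.62 with 0 of 31 called by edgeR (0 adjusted over the list alone), and camera's adjusted p rose from 1.89e-12 to 0.117 with an estimated correlation. The median of all genes was -0.05 with TMM scaling and -0.12 with library size only. The 2 CA1 lines differed too, but the 3 Sstr4 libraries are of run A and the 6 Cck libraries of runs B and D, so line and number run cannot be told apart. In the Cck line (n = 6) against the Sstr4 line (n = 3), the interneuron peptide gene Sst was at 13.3 ± 2.51 against 172 ± 57 CPM, C1ql2 of granule cells at 1.95 ± 0.656 against 24.2 ± 4.29 and Pla2g4e lower by log2 -3.90 ± 0.44. Calb2, which encodes calretinin, was at 38 ± 8.92 against 6.33 ± 1.43 CPM, and Crispld1 and Abracl were higher by 1.79 and 1.74. Between these lines 210 genes were called higher and 770 lower of 15004. DG granule markers were lower in 11 of 12 (11 adjusted over the list alone, median -1.85, camera adjusted p = 0.000209 with an estimated correlation) and interneuron markers in 12 of 14 (12 adjusted over the list alone, median -1.89, camera adjusted p = 0.000796 with an estimated correlation).

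CA2 libraries stood out by genes of CA2 and of another cell type. Cacng5, Rgs14, Necab2 and Pcp4, which mark CA2, were higher by 4.37, 3.60, 3.21 and 3.11 on the log2 scale. The genes with the largest differences were Sln (7.23 ± 0.66), the transcription factor genes Eomes (7.20 ± 0.65), Prdm12 and Dmrtb1, and Glp1r, which encodes the receptor for GLP-1 (40.4 ± 58.8 CPM, n = 9, against 1.25 ± 1.6). Pdgfra and Olig1, which mark oligodendrocyte precursors, were higher by 6.16 and 5.77. Immediate early genes were lower in 3 of 18 (3 adjusted over the list alone, median -0.67, camera adjusted p = 0.0232 with an estimated correlation). edgeR's test called 1977 genes higher and 809 lower. All 9 CA2 markers were higher (9 adjusted over the list alone, median 3.39, camera adjusted p = 1.65e-09 with an estimated correlation), and so were all 9 precursor markers (9 adjusted over the list alone, median 5.72, camera adjusted p = 0.000566 with an estimated correlation). The oligodendrocyte markers, 14 of 16 higher with a median of 2.32 (14 adjusted over the list alone), gave 0.0558 and the interneuron markers, 11 of 14 with a median of 1.57 (11 adjusted over the list alone), 0.072 with an estimated correlation.

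In CA3 the iodotyrosine deiodinase gene Iyd was at 27.4 ± 2.53 CPM (n = 3) against 0.613 ± 0.902 (n = 47), a log2 difference of 7.36 ± 0.50, and the retinoic acid hydroxylase gene Cyp26b1 at 93.5 ± 20.1 against 5.34 ± 4.87. The apoptosis gene Bok, a CA3 marker, was higher by 3.45. Klk8 and Klk10 were higher by 5.24 and 6.02 and the antisense gene Spag17os by 5.83, all uncertain because their reads can be shared. edgeR's test called 1146 genes higher and 1317 lower. CA3 markers were higher in 7 of 9 (7 adjusted over the list alone, median 2.69, camera adjusted p = 9.1e-10 with an estimated correlation). Astrocyte, oligodendrocyte and interneuron markers were lower in 11 of 15, 13 of 16 and 11 of 14 (11, 16 and 12 adjusted over the list alone), with medians of -2.26, -1.87 and -2.43, and mitochondrially encoded genes in 7 of 7 (7 adjusted over the list alone), with a median of -3.14. None of these 4 lists kept camera's call with an estimated correlation, where the adjusted p were 0.306, 0.352, 0.23 and 0.352. The median of all genes was -0.06 with TMM scaling and -0.23 with library size only.

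Granule cells of the DG were higher in the complement-like synaptic gene C1ql2, at 94.8 ± 35.3 CPM (n = 3) against 3.92 ± 5.84 (n = 47), and in Dsp, which encodes desmoplakin, at 141 ± 15.7 against 11.9 ± 18.9. Capn3 was higher by 4.94, Clec1a by 5.71 and Pla2g2f by 5.59, and Prox1, the transcription factor gene that defines granule cells, by 4.57. edgeR's test called 845 genes higher and 573 lower. All 12 granule cell markers were higher (12 adjusted over the list alone, median 3.45, camera adjusted p = 4.61e-06 with an estimated correlation). Choroid plexus markers, a sign of tissue next to the dentate gyrus, had 6 of 10 higher (7 adjusted over the list alone, median 2.71, camera adjusted p = 0.456 with an estimated correlation).

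The neocortical types S1 and V1 were each compared with the 6 others. Rorb, a gene of layer IV, was higher in S1 by 3.80 and in V1 by 5.28 on the log2 scale, and Rspo1, a Wnt agonist, by 4.22 ± 0.52 and 6.41 ± 0.58. In S1 the synaptic gene Rims3 was higher by 3.31, and Igfn1 and the immunoglobulin gene Ighg2c were among the 5 with the largest differences. Kalrn, which encodes a synaptic exchange factor, held 61600 ± 11700 CPM in S1 (n = 6) against 4190 ± 3370 (n = 44); the reason for so high a value was not examined, so it is uncertain as a measure of expression. In V1 Shisa3 was higher by 6.61 ± 0.72, Endou by 6.17, Adam33 by 5.85 and the antisense gene Prox2os, which is uncertain, by 6.10. Called genes numbered 2370 higher and 1056 lower in S1, and 1971 and 1279 in V1. Neocortical projection markers were higher in 10 of 17 in both (10 adjusted over the list alone in each), with medians of 1.54 and 1.5 (camera adjusted p = 1.56e-07 and 1.92e-08 with an estimated correlation). In V1 presynaptic genes had 13 of 42 higher (13 adjusted over the list alone, median 0.48, camera adjusted p = 0.0496 with an estimated correlation). In S1, markers of oligodendrocytes, microglia and astrocytes were higher in 15 of 16, 15 of 18 and 12 of 15 (15, 15 and 12 adjusted over the list alone), and camera's adjusted p with an estimated correlation were 0.205, 0.263 and 0.0634. All 7 mitochondrially encoded genes were higher in both types (7 adjusted over the list alone), with medians of 2.90 and 3.14 and camera's adjusted p 0.205 and 0.112 with an estimated correlation. In S1 they averaged 7.06 log2 CPM in replicate 1 and 4.61 to 5.44 in the others. The V1 libraries, all of run D, had 11.93 to 14.81% of reads aligned to several places, where the median of all libraries was 24.14%. Within V1 these genes were lower at 12 and 24 months.

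The vulnerable ECII and CA1 neurons were next compared with the 5 more resistant types, to ask what they share. Dcn was at 69.3 ± 61.1 CPM (n = 26) against 4.01 ± 7.01 (n = 24), a log2 difference of 4.26 ± 0.32, and Fibcd1 at 57.1 ± 60.2 against 6.69 ± 6.28. The pooled means hide differences between these types. Fibcd1 averaged 14.9 ± 6.13 CPM in ECII (n = 17), 137 ± 17.9 in CA1 (n = 9) and 18.5 ± 2.68 in DG (n = 3), and Dcn 97.8 ± 57.7, 15.6 ± 4.97 and 21.8 ± 1.84. Myelin genes were lower, with Gjc3 and Enpp6 at log2 -2.48 and -2.61, and so were Rspo1 (-3.42), Cpne9 (-3.04), Ccbe1 (-2.55), Hr, Gcnt4, Sema5b and Cbln2. The sodium channel subunit gene Scn3b and the vesicle gene Rab3c were higher by 1.21 and 1.28, and the splicing factor gene Nova1 lower by -1.04. Oxidative phosphorylation genes had a median of 0.49 and voltage-gated potassium channels of -0.19. Acta2, Actg2, Cnn1, Map3k7cl, Higd1b, Aspn, Cbr2 and Lmod1 were also among those with the largest differences upward. Acta2 averaged 671 ± 1270 CPM in ECII and 1.77 ± 0.876 in CA1, and Actg2 13.2 ± 23.8 and 0.0343 ± 0.0602, so neither is shared by both types. edgeR's test called 921 genes higher and 600 lower, 1521 in all, where limma-voom with the line as a block called 535 and edgeR without the Rasgrp2 lines 1826. Oligodendrocyte markers were lower in 14 of 16 (14 adjusted over the list alone, median -2.05, camera adjusted p = 0.0048 with an estimated correlation) and precursor markers in 7 of 9 (7 adjusted over the list alone, median -1.68, camera adjusted p = 0.0231 with an estimated correlation). These lists do not part the 2 types from all others: oligodendrocyte markers averaged 1.99 ± 1.11 log2 CPM in ECII, 3.30 in CA1 and 2.70 in CA3, against 6.03 in CA2 and 5.82 in S1, and precursor markers 1.2, 0.92 and 0.01 against 6.83 and 3.17. Oxidative phosphorylation had 0 of 75 called by edgeR (0 adjusted over the list alone) and potassium channels 4 of 34 lower (4 adjusted over the list alone); camera's adjusted p, 3.04e-16 and 3.3e-08, rose to 0.227 and 0.0802 with an estimated correlation.

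Within each type, older mice were compared with those of 4-5 months, to ask how ageing changes each kind of neuron. Age and number run overlap, so values from run B, the only run with both ages, are given where it has both. In ECII at 12 months the calcium-binding gene S100a6 rose by 2.07 ± 0.40, from 10.2 ± 7.49 (n = 17) to 40.4 ± 20.2 CPM (n = 10), Rarres2 by 1.70 ± 0.49 and Tm4sf1 by 1.60 ± 0.44. The synapse organiser gene Cbln1 fell from 55.2 ± 28.7 to 20.6 ± 15.2 CPM, Il1rapl2 by log2 -1.48 and Fam163a by -1.37. App was lower by -0.42 ± 0.11, and the vesicle priming gene Unc13a by -0.71. Ribosomal protein genes rose as a group, Rps29 by 1.24, and 13 of 26 calcium and sodium channel genes fell (20 adjusted over the list alone), with a median of -0.40. edgeR's test called 1521 genes higher and 1048 lower of 16714. The ribosomal proteins had 66 of 76 higher (70 adjusted over the list alone, median 0.72, camera adjusted p = 0.00481 with an estimated correlation), and oxidative phosphorylation 48 of 75 (55 adjusted over the list alone, median 0.43, camera adjusted p = 0.103 with an estimated correlation). The channels gave camera's adjusted p = 0.103 with an estimated correlation. Within run B, 2 libraries at 12 months and 3 at 4-5 months of founder #26, 246 genes were higher and 439 lower, the ribosomal proteins had a median of 0.49 and oxidative phosphorylation of 0.44. Endothelial and mural markers (median -1.50), oligodendrocyte precursor markers (-1.43) and astrocyte markers (-0.53) were lower there (camera adjusted p = 0.00458, 0.00458 and 0.0482; 2, 2 and 0 members called). The channels had a median of 0.08 with 1 of 26 lower, so their fall was not seen within run B, and App was higher by 0.52 ± 0.16, not called. At 4-5 months App was lower in run B than in run A of this founder, by log2 -0.885 ± 0.149 (edgeR's test, adjusted p = 0.0123). In 1 fit over the wild-type libraries 2811 genes were called without the number run and 19 with it as a covariate. Run C does not enter this contrast. In the latter fit the effects of runs A, B and D are set by lines with 4-5-month libraries in several of them. These are both Sh3bgrl2 founders and the Cck, Cacng5 and Cartpt lines.

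In ECII at 24 months the astrocyte connexin gene Gja1 rose by 1.41 ± 0.24 (n = 12 against 17). Axl, Pros1, Fbln5, Il13ra1, Osmr, Npas3, Abcb1a and Oasl2 rose by 1.22 to 1.5. C4b, a complement component, was higher by 2.13 ± 0.40 and the microglia marker Ctss, a protease gene, by 2.38. Ttr, the choroid plexus transport protein, fell by 4.14 on the log2 scale (± 1.32), with 7.52 ± 12.2 against 192 ± 321 CPM. Rpl13 fell from 60.1 ± 22.6 to 22.7 ± 4.82 CPM, and Myl6b, Yjefn3, Zfp428, Rpph1, Ube2s and Myl4 by log2 -1.24 to -1.43. Hist2h4, whose reads may be shared with other histone genes, was lower by -2.05. edgeR's test called 2597 genes higher and 1859 lower. Ribosomal proteins were lower in 67 of 76 (67 adjusted over the list alone, median -0.59, camera adjusted p = 0.0805 with an estimated correlation), against the direction at 12 months. Oxidative phosphorylation genes were lower in 49 of 75 (52 adjusted over the list alone, median -0.36, camera adjusted p = 0.22 with an estimated correlation). Astrocyte markers rose in 7 of 15 (8 adjusted over the list alone, median 0.63, camera adjusted p = 0.515 with an estimated correlation). No number run holds ECII libraries of both 24 and 4-5 months. The fit over the wild-type libraries called 4965 genes without the run and 204 with it as a covariate, where Gja1, Pros1 and Osmr reversed to -0.20, -0.059 and -0.12. With this covariate the effect of run C is set by 3 CA2 libraries alone.

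In CA1 C4b was at 14.3 ± 8.43 CPM at 24 months (n = 6) and 0.57 ± 0.6 at 4-5 months (n = 9), a log2 change of 4.68 ± 0.44 (edgeR's quasi-likelihood test, adjusted p = 1.07e-07; higher in 6 of 6 libraries than the mean at 4-5 months). In the fit over the wild-type libraries C4b was higher by 4.56 without the number run and reversed to -0.66 with it as a covariate. That fit called 2382 genes at 24 and 723 at 12 months without the run, and 0 and 758 with it; no run holds CA1 libraries of both 24 and 4-5 months. App rose from 408 ± 90.7 to 865 ± 118 CPM, its relative Aplp2 by 1.18, the cell adhesion gene Pcdhb9 by 2.06 ± 0.18 and the proteoglycan gene Cspg4 by 1.91. The cholesterol synthesis gene Cyp51 rose by 1.30 and the receptor gene Gria2 by 0.95. Ttr fell by 3.60 on the log2 scale, Igf2 by 1.5 and Zic1 by 1.42. At 12 months App was higher by 0.56, Prnp by 0.74, Apmap by 1.29 ± 0.13 and Cspg4 and Zc3hav1 by 1.46 and 1.30, while the nuclear RNA Malat1 fell by 1.13 on the log2 scale and Rn7sk and Rpph1 were lower. edgeR's test called 1954 genes higher and 1958 lower of 15447 at 24 months, and 1092 and 1047 at 12 months. Beta protocadherins were higher in 16 of 22 at 24 months (18 adjusted over the list alone, median 1.24, camera adjusted p = 0.00325 with an estimated correlation), though paralogs of this cluster can share reads. Cholesterol synthesis had 17 of 23 (17 adjusted over the list alone, median 0.51, camera adjusted p = 0.000985 with an estimated correlation), and 9 of 23 at 12 months (11 adjusted over the list alone, camera adjusted p = 0.012 with an estimated correlation). Ribosomal proteins were lower in 70 of 76 (72 adjusted over the list alone, median -0.67), glutamate receptors higher in 15 of 24 (15 adjusted over the list alone, median 0.58) and astrocyte markers in 9 of 15 (9 adjusted over the list alone, median 0.70), with camera's adjusted p 0.188, 0.147 and 0.0928 with an estimated correlation. Within run B, 3 libraries of each age of the Cck line at 12 months, 1213 genes were higher and 192 lower, C4b was higher by 3.19 ± 0.55 and App by 0.92 ± 0.11, and cholesterol synthesis had 9 of 23 higher. Plaque-associated glial genes, a list that includes C4b, were higher there in 8 of 22 (median 0.73, camera adjusted p = 2.55e-05). Interneuron markers were higher in 3 of 14 (median 0.20, camera adjusted p = 0.017), and astrocyte and microglia markers were not called.

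In DG C4b rose from 1.68 ± 0.946 to 77.7 ± 53.1 CPM at 24 months (n = 3 each), a log2 change of 5.51 ± 0.54 (edgeR's test, adjusted p = 7.58e-05; higher in 3 of 3 libraries). In the fit over the wild-type libraries C4b was higher by 5.55 without the number run and by 0.04, not called, with it as a covariate. That fit called 1901 genes at 24 and 189 at 12 months without the run, and 19 and 29 with it. App rose from 511 ± 33.7 to 1660 ± 674 CPM, the oncostatin receptor gene Osmr by 3.37 ± 0.64 and Reln from 16.2 ± 1.17 to 148 ± 96.4 CPM. Edf1, Selenom and Cstad fell by 2.03, 1.94 and 2.43 on the log2 scale. At 12 months Npy was at 120 ± 182 CPM against 5.42 ± 2.07, but ran from 12.8 to 330 CPM. Its log2 change of 4.47 was 1.57 without replicate 3, and it was not called without any 1 of the 4-5-month libraries. Igfbp6 was higher by 2.72 and C4b by 2.44, and Tsc22d1, Atn1 and Ost4 fell by 1.36, 1.27 and 1.22. edgeR's test called 1551 genes higher and 1145 lower of 15176 at 24 months, and 313 and 119 at 12 months. At 24 months microglia markers rose in 15 of 18 (16 adjusted over the list alone, median 1.78), astrocyte markers in 11 of 15 (12 adjusted over the list alone, median 1.42), complement genes in 7 of 11 (7 adjusted over the list alone, median 1.74) and beta protocadherins in 16 of 22 (19 adjusted over the list alone, median 1.23). Camera's adjusted p with an estimated correlation were 0.143, 0.143, 0.143 and 0.171. At 12 months ribosomal proteins were higher in 47 of 76 (65 adjusted over the list alone, median 1.02, camera adjusted p = 0.181 with an estimated correlation). Leaving out single libraries moved these counts. Without replicate 1, 2 or 3 of 12 months they were 191, 192 and 104, without replicate 1 of 24 months 680, and without replicate 2 or 3 of 4-5 months 109 and 80, all at 12 months. At 24 months they were 1178 without replicate 1 of that age and 1012 without replicate 2 of 4-5 months.

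In CA3 at 24 months Pcdhb9 rose from 3.51 ± 0.424 to 11.1 ± 2.33 CPM (n = 3 each) and the extracellular matrix gene Frem3 by 1.82 ± 0.41, and Rorb was higher by 1.83 ± 0.43. Zfp771 fell from 28.6 ± 2.16 to 8.72 ± 1.71 CPM, and Stpg1 and Csf2ra by 1.99 and 1.73 on the log2 scale. At 12 months the ATP synthase subunit gene Atp5mpl rose from 119 ± 32 to 316 ± 26.2 CPM, Otos by 1.65 and Tmed2 by 1.38, and the AMPA receptor subunit gene Gsg1l fell by 2.69, Cpne2 by 2.11 and Ttr by 4.19. edgeR's test called 1277 genes higher and 1469 lower of 14942 at 24 months, and 1336 and 1374 at 12 months. Beta protocadherins were higher in 10 of 21 at 24 months (13 adjusted over the list alone, median 0.97, camera adjusted p = 0.0326 with an estimated correlation) and cholesterol synthesis in 11 of 23 (14 adjusted over the list alone, median 0.47, camera adjusted p = 0.221 with an estimated correlation). Ribosomal proteins were higher in 49 of 76 at 12 months (60 adjusted over the list alone, median 0.57, camera adjusted p = 0.352 with an estimated correlation). Without replicate 1 of 12 months the count at 12 months was 1576. That at 24 months was 1582 without replicate 2 of that age, and 1707 and 1642 without replicates 1 and 3 of 4-5 months. The fit over the wild-type libraries called 248 genes at 12 and 188 at 24 months without the number run, so most of the fall in these counts came with the pooled fit, and 14 and 0 with the run as a covariate. Without the run Pcdhb9 at 24 and Atp5mpl at 12 months were not called (1.65 and 1.37), and with it they reversed to -0.22 and -0.32. All CA3 and DG libraries of 4-5 months had numbers of run A, so age and run cannot be told apart within these types.

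In S1 at 24 months C4b rose from 2.51 ± 2.22 (n = 6) to 33.6 ± 6.44 CPM (n = 3), App from 561 ± 88.7 to 1550 ± 232 CPM and the lysosomal cholesterol transporter gene Npc1 by 1.83. In the fit over the wild-type libraries C4b was higher by 3.66 without the number run and reversed to -1.19 with it as a covariate. That fit called 2385 genes at 24 and 690 at 12 months without the run, and 13 and 319 with it. Bmp6 and Abca8a rose by 4.83 ± 0.86 and 3.16 ± 0.52, and the histone demethylase gene Kdm6b fell from 367 ± 143 to 103 ± 17.6 CPM, with Sox4 and Mrpl52 lower by -2.12 and -1.83. edgeR's test called 71 genes higher and 50 lower of 16359. Astrocyte markers were higher in 3 of 15 (9 adjusted over the list alone, median 0.68, camera adjusted p = 0.00912 with an estimated correlation) and microglia markers in 2 of 18 (4 adjusted over the list alone, median 0.89, camera adjusted p = 0.00912 with an estimated correlation). Genes of APP processing were higher in 2 of 14 (3 adjusted over the list alone, median 0.48, camera adjusted p = 0.016 with an estimated correlation) and beta protocadherins in 1 of 21 (7 adjusted over the list alone, median 0.87, camera adjusted p = 0.016 with an estimated correlation). Ribosomal proteins were lower in 2 of 76 (54 adjusted over the list alone, median -1.08, camera adjusted p = 0.175 with an estimated correlation). Without 1 of the 12-month libraries, replicates 1 to 3, the count was 38, 53 and 56, and without 1 of the 24-month libraries 4, 5 and 18. With the run A libraries of 4-5 months left out it was 1538. At 12 months edgeR called 0 genes in S1, with 1251 at an unadjusted p under 0.05 and 58 called by DESeq2, and 2 in run B alone, 3 libraries of each age.

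In V1 at 12 months Lars2, a mitochondrial tRNA synthetase gene, rose from 1080 ± 240 to 13300 ± 1550 CPM (n = 3 each). The reason for so high a value was not examined, so Lars2 is uncertain as a measure of expression. Mitochondrially encoded genes fell, with medians of -2.02 at 12 and -3.55 at 24 months. Other measures of the libraries differed too: reads that aligned to several places were 11.93 to 14.81% at 4-5 months and 19.25 to 27.35% later, and the 10 most abundant genes held 8.56 to 10.75% and 12.92 to 18.21% of the counts. At 24 months the adhesion gene Fermt1 rose from 2.7 ± 1.31 to 43.8 ± 5.84 CPM, and Adgrf5, a gene of blood vessels, fell from 20.5 ± 3.45 to 0.307 ± 0.216 CPM. Ttr was lower by -6.46 and Tspan18 by -5.59, and Mir6236 and Hist1h1a, which can share reads with other genes, were higher. At 12 months Hes5 and Pi4k2b were higher by 3.69 and 4.56, and Tspan18, Fcer2a and Slc26a1 lower by -4.96, -4.70 and -4.48. edgeR's test called 1169 genes higher and 1012 lower of 15590 at 12 months, and 817 and 1054 at 24 months. Mitochondrially encoded genes were lower in 6 of 7 and 7 of 7 (6 and 7 adjusted over the list alone, camera adjusted p = 0.195 and 0.181 with an estimated correlation). At 12 months ribosomal proteins were higher in 55 of 76 (65 adjusted over the list alone, median 1.14, camera adjusted p = 0.164 with an estimated correlation), and at 24 months oligodendrocyte markers were lower in 9 of 16 (13 adjusted over the list alone, median -1.26, camera adjusted p = 0.202 with an estimated correlation). Without replicates 2 and 3 of 12 months the 12-month count was 1233 and 928. At 24 months it was 682, 731 and 978 without each library of that age and 1199 without replicate 2 of 4-5 months. The fit over the wild-type libraries called 3196 and 2828 genes at 12 and 24 months without the number run, and 547 and 1047 with it as a covariate. All 4-5-month V1 libraries were of run D, so age and run cannot be told apart.

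CA2 had libraries at 4-5 and 12 months. C4b was at 2.96 ± 1.44 CPM at 12 months (n = 3) and 13.4 ± 25.9 at 4-5 months (n = 9), and App at 349 ± 9.76 and 452 ± 157. edgeR called 0 of 16088 genes, with 1227 at an unadjusted p under 0.05, and DESeq2 called 10. The 3 CA2 libraries of 4-5 months in run C, replicates 7 to 9, differed from the 6 others of that age by 5.07 ± 0.48 for C4b and 1.82 ± 0.32 for Pcdhb9 on the log2 scale. They carry the mean of C4b at 4-5 months, where it ran from 0.607 to 79.8 CPM over the 9 libraries. App was higher in them by 0.76 ± 0.23, not called. Of 15511 genes 2 were called by edgeR between these CA2 libraries, and 2304 had an unadjusted p under 0.05. Their beta protocadherins had a median of 0.92 and their ribosomal proteins of -0.72. Within run B, 3 libraries of each age, 376 genes were higher at 12 months and 211 lower. Markers of other cells moved there too: interneuron markers were higher in 10 of 14 (median 0.66) and oligodendrocyte precursor markers in 6 of 9 (0.63), and oligodendrocyte markers lower in 3 of 16 (-0.50).

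**Figure D2:**
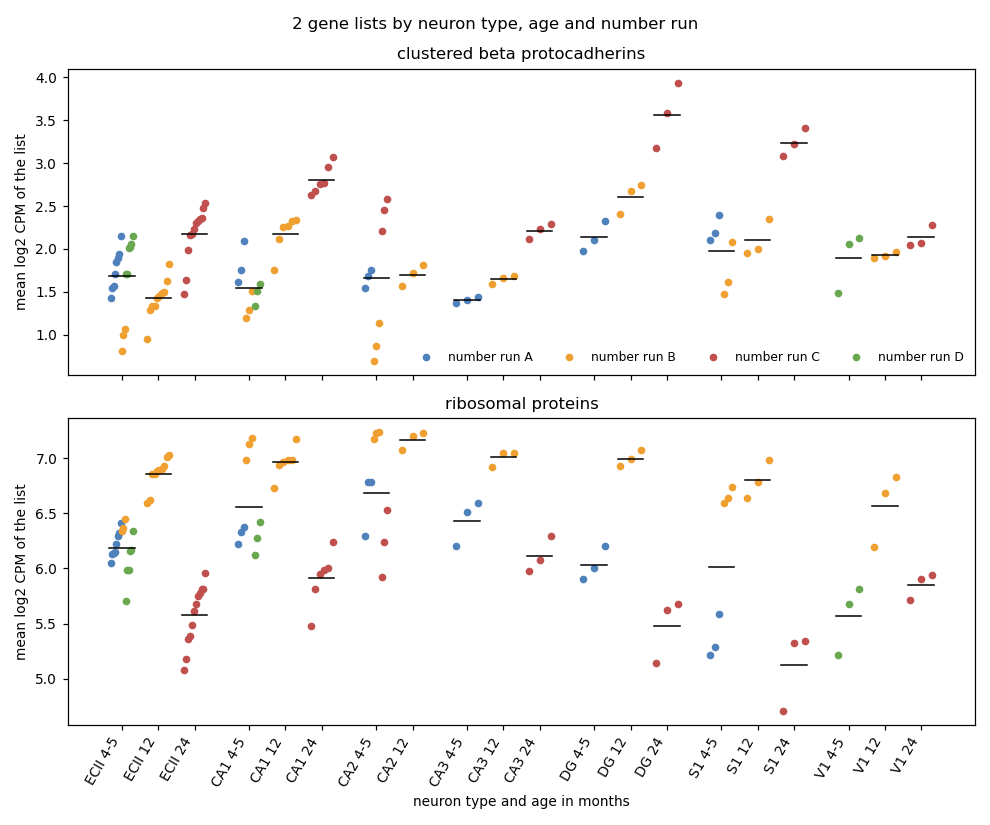
Mean log2 CPM of the clustered beta protocadherins and of the ribosomal proteins in each library, by neuron type and age; each point is 1 library coloured by its number run and each bar a group mean. All 24-month libraries have numbers of run C, as do 3 of the 9 CA2 libraries of 4-5 months.

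The 24-month comparisons were set side by side to ask which changes neuron types share. The ascorbate transporter gene Slc23a2 and Gucy1b1 were called higher in all 6 types. Pcdhb9 and the sterol gene Msmo1 were higher in 5 types. The postsynaptic calmodulin-binding gene Nrgn was lower in all 6, by -0.33 in ECII to -1.49 in DG. Of 13818 genes tested in all 6 types, 816 were higher and 835 lower in at least 3, where 302.4 were expected if the calls of each type were shuffled and the highest of 1000 shuffles gave 354. In at least 4 types there were 652, against 17.3. Of the genes called in at least 5 types, 46 were higher and 48 lower. All 24-month libraries share number run C.

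**Figure D3:**
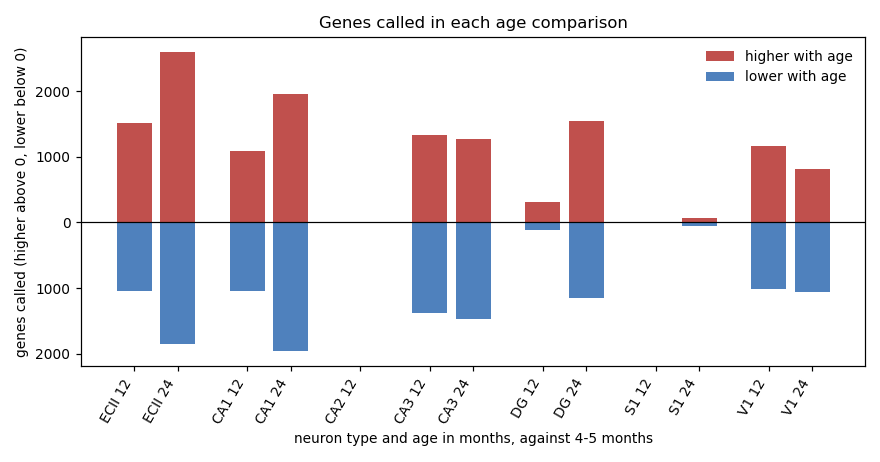
Genes called by edgeR in each age comparison, the number higher in older mice above 0 and the number lower below 0. At 24 months the counts ran from 121 in S1 to 4456 in ECII.

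Whether ageing changes ECII neurons in another way than other neurons was tested as a difference between the 24-month changes of ECII and the mean of those of CA1, CA3, DG, S1 and V1. The change of App was smaller in ECII than this mean, by a log2 difference of -0.69 ± 0.14 (edgeR's quasi-likelihood test, adjusted p = 0.000275). The mean rests on CA1, DG and S1: App changed by 0.20 in ECII, 1.03 in CA1, 1.69 in DG and 1.43 in S1, but by 0.04 in CA3 and -0.01 in V1. App also differed between number runs A and B at 4-5 months, in CA2 and in ECII founder #26. The runs of the 4-5-month libraries were not the same in each type. The chaperone gene Hspa8 (-0.97) and the NMDA receptor gene Grin1 (-1.07) differed the same way. Emx2 and its antisense Emx2os, which share reads, were higher by 1.96 and 2.14, and Tmem252, Dgkk and Dmpk by 2.83, 2.09 and 2.06. Pcdhb2, Mir6236, Thbs2, Chpf2 and Casp1 were lower by -1.92, -2.00, -1.55, -1.49 and -1.43. edgeR's test called 887 genes higher and 957 lower of 21177, and 1712 without the Rasgrp2 lines. Autophagy and lysosome genes were lower in 15 of 34 (20 adjusted over the list alone, median -0.41, camera adjusted p = 0.0122 with an estimated correlation). Cholesterol synthesis was lower in 11 of 23 (13 adjusted over the list alone, median -0.46, camera adjusted p = 0.0186 with an estimated correlation) and heat shock genes in 12 of 31 (12 adjusted over the list alone, median -0.37, camera adjusted p = 0.0186 with an estimated correlation).

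ECII neurons of APP/PS1 mice, which carry human transgenes and form amyloid, were compared with those of mice without them. Prnp was at 1370 ± 293 CPM with the transgenes (n = 8) and 443 ± 234 without (n = 3), a log2 difference of 1.62 ± 0.32 that was not called (edgeR's quasi-likelihood test, adjusted p = 0.462), and all 8 libraries were above the 3 others. DESeq2 called Prnp (1.54 ± 0.36, adjusted p = 0.00418) and so did limma-voom with library weights (2.04 ± 0.22, adjusted p = 0.000718); edgeR with length and GC offsets did not (1.02 ± 0.51, adjusted p = 0.378). App averaged 588 ± 111 against 432 ± 38.5 CPM (edgeR's test, adjusted p = 0.638). Immediate early genes had a median of -0.86, endothelial and mural markers of -1.06 and presynaptic genes of -0.28. edgeR called 0 of 14673 genes, with 1241 at an unadjusted p under 0.05, where DESeq2 called 255, limma-voom with library weights 20 and edgeR without replicate 1 of the mice without transgenes 1. That library had a weight of 0.09, and its values raise doubt about its ECII label: Sh3bgrl2 was at 30.1 CPM against 193 and 120 in the 2 others, Rasgrp2 at 1.23 against 25.6 and 13.2 and Rgs14 at 128 against 15.7 and 16.7, though Reln was at 612 against 732 and 439. The immediate early, endothelial and presynaptic lists had 0 members called (0 adjusted over the list alone), and camera's adjusted p were 0.0425, 0.0425 and 0.0214, and 0.88, 0.943 and 0.943 with an estimated correlation. The median of all genes was 0.07 with TMM scaling and 0.17 with library size only. Of the 200 genes with the smallest p in each direction, 4 higher and 5 lower were also among the 200 of ageing ECII neurons at 24 months, where 2.75 were expected (Fisher's exact test, p = 0.358 and 0.203). Planted 2-fold changes were recovered at 3% in this design.

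Over all comparisons camera called 356 of 875 list tests, of which 44 held with an estimated correlation. Among age comparisons these were ribosomal proteins in ECII at 12 months, cholesterol synthesis in CA1 at both ages, beta protocadherins in CA1, CA3 and S1 at 24 months, and astrocyte, microglia, complement, APP processing, risk locus and plaque-associated genes in S1 at 24 months. For the difference between types they were autophagy, cholesterol synthesis and heat shock genes. The markers of each type held in their own identity comparison.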

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

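All tests of the 3 patterns weighed here were chosen after the result was seen; the tests for values far from their group and the regroupings of libraries were planned.

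In 132 tests of groups of 4 to 10 libraries, 13 values lay far from the others of their group, and chance flags about 1 in 20 groups, or 6.6 of these tests. In CA1 at 4-5 months the microglia markers averaged -1.68 log2 CPM in replicate 9 against -0.85 to -0.26 in the others, Ptbp1 was at 28.7 CPM in replicate 3 against 8.15 to 13.8, and Xist, transcribed from the inactive X of females, at 0.195 CPM in replicate 2 against 0 to 0.0701. In CA2 at 4-5 months the endothelial and mural markers averaged 1.93 in replicate 1 against -1.67 to -0.78, and Xist was at 0.472 CPM in replicate 2 against 0 to 0.0638. In S1 at 4-5 months replicate 1 detected 16514 genes against 17755 to 18085, and its mitochondrially encoded genes averaged 7.06 against 4.61 to 5.44. In ECII at 12 months the choroid plexus markers averaged 3.85 in replicate 10 against -1.15 to 1.34, and Xist was at 5.92 CPM in replicate 3 against 0 to 0.0533. The Y-linked genes Ddx3y and Eif2s3y were at 0 and 0.199 CPM in that library against 12.4 to 44 and 8.08 to 20.5 in the others of the group, so its male label is in doubt. Without it 2169 genes were called in ECII at 12 months. In CA1 the 10 most abundant genes held 11.25% of the counts in replicate 6 of 12 months against 16.44 to 18.72%, and choroid plexus markers averaged 2.32 in replicate 5 of 24 months against -0.75 to -0.14. With the APP/PS1 transgenes, endothelial and mural markers averaged -3.16 in replicate 4 against -1.63 to -0.31, and App was at 849 CPM in replicate 7 against 502 to 610.

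The change from 4-5 to 24 months differed between ECII and the mean of the 5 other types for 1844 genes by edgeR's test. Those named were Tmem252 (log2 difference 2.83), Emx2os (2.14), Dgkk (2.09), Dmpk (2.06) and Emx2 (1.96), and, in the other direction, Mir6236 (-2.00), Pcdhb2 (-1.92), Thbs2 (-1.55), Chpf2 (-1.49) and Casp1 (-1.43).

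The rise of beta protocadherins, C4b and App at 24 months was weighed against 3 technical explanations. For the beta protocadherins, RNA of glial cells as the whole cause is argued against in CA3, where their median exceeded that of 46 glial markers by 0.951 with an SD of 0.776 among the markers. It may be a cause in DG, where the difference was -0.251, with medians of 1.78 for microglia and 1.42 for astrocyte markers. For C4b a like rise of all glial RNA as the whole cause is argued against. Its change exceeded the pooled median of astrocyte, oligodendrocyte and microglia markers by 1.506 in ECII, with an SD of 0.578 among the markers. In CA1, DG and S1 it exceeded this median by 4.09, 4.04 and 3.02. A larger share of a single glial type was not tested. In ECII the microglia marker Ctss rose more than C4b. A rise of C4b within glial cells whose RNA is present was not tested. For App glial RNA stays open: 1 of its 3 called rises exceeded the glial median by more than the SD, and in DG it exceeded it by 0.216 with an SD of 0.738. In CA3 App was not called, at 0.04 ± 0.09. Other number runs differed at 4-5 months too. App was called lower in run B than in run A in CA2 (-0.696) and ECII founder #26 (-0.885), but not in S1 (-0.274). Beta protocadherins were called lower in run B in CA2 (median -0.71), but not in ECII founder #26 (-0.167). Number run C may raise the genes of this pattern, since the 3 CA2 libraries of that run, labelled 4-5 months, had a beta protocadherin median 0.921 above that of the 6 others. A wrong age label on these 3 libraries could give the same picture: their C4b was higher by 5.07, between the 2.13 and 5.51 by which 4 types changed at 24 months. Within run B, where the run is the same, beta protocadherins were called higher at 12 months in 2 of 4 types, CA1 (median 1.07) and CA2 (0.60), and in CA1 so were C4b (3.19) and App (0.92). The run cannot explain these rises at 12 months. Markers of other cells moved with them in CA2, where interneuron markers (0.66) and oligodendrocyte precursor markers (0.63) were called higher. Plaque-associated glial genes, a list that includes C4b, were called higher in CA1 (0.73) and CA2 (0.57). In CA1 within run B astrocyte and microglia markers were not called. Interneuron markers (0.20), calcium and sodium channels (0.86) and glutamate receptors (0.78) were called higher there. A difference in the make-up of these libraries stays open. Beta protocadherins, C4b and App were not called in ECII and S1 within run B. At 24 months run C and age cannot be told apart, and ageing stays open as a cause.

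Ribosomal protein and oxidative phosphorylation genes were higher at 12 months and lower at 24 months in ECII and CA1. Gene length and GC content as the whole cause are argued against. With offsets for both the ribosomal median in ECII at 24 months was -0.41, with an SE of 0.049 over the member genes. Camera still called the list at a correlation of 0.01. Without offsets it was not called with an estimated correlation (camera adjusted p = 0.0805). The number run may contribute: at 4-5 months ribosomal proteins were higher in run B than in run A in all 3 contrasts, with medians of 0.632 in CA2, 0.25 in ECII founder #26 and 1.31 in S1. In CA1 run B holds both ages of the Cck line alone, 3 libraries of each. There the ribosomal median was -0.043 with 0 of 76 members called, against 0.382 over all runs and both lines. That of oxidative phosphorylation was 0.032. The SE of the ribosomal median, 0.009, is a spread between member genes, not between libraries. For the Cck line these values argue against age as the cause of the 12-month rise. The Sstr4 line could not be tested within a run. Within run B the ribosomal list was called higher in ECII, with a median of 0.486, so a change with age in ECII stays open. In this contrast the medians of vessel (-1.50), oligodendrocyte precursor (-1.43) and astrocyte markers (-0.53) were lower too. Thy1 was at 261 to 413 CPM in its 3 libraries of 4-5 months, against 927 and 1150 in those of run A of the same founder, so a difference in the make-up of these libraries stays open as well.

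Blood vessel genes were high in the Rasgrp2 ECII lines. A lower share of neurons would raise markers of all other cells alike and is argued against, since the vessel median exceeded the next highest, 1.90 for oligodendrocytes, by 3.462 with a pooled SD of 1.61. The number run is argued against, since within run A alone the vessel median was 6.15 and all 15 members were called. A candidate explanation is activity of the Rasgrp2 BACs in vessel cells, which was not tested, and no biological explanation beside the line was tested.

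For each count of called genes the libraries were regrouped in the same sizes, the real grouping included. For all 7 identity counts 1 of 60 regroupings, the real one, was as large, a share under 0.05. The counts and the highest of the others were 3296 and 675 for ECII, 2546 and 754 for CA1, 2786 and 340 for CA2, 2463 and 1121 for CA3, 1418 and 248 for DG, 3426 and 44 for S1, and 3250 and 442 for V1. The share was also 1 of 60 for ECII with CA1 (1521 and 698) and the lines of ECII (2760 and 148) and of CA1 (980 and 191). The same held for ECII at 12 months (2569 and 10) and 24 months (4456 and 0) and CA1 at 24 months (3912 and 1). It held as well for the difference between types, counted here by limma-voom (1790 and 171). The regroupings moved libraries singly without regard to number run, and in the identity and line comparisons across lines. They cannot tell type, age or line from number run, nor a type with a single line from that line. For CA1 at 12 months 2 of 60 were as large, with 2139 and 2758. The highest set the 6 libraries of 4-5 months in runs A and D against all libraries of run B, and the count within run B alone was 1405. For S1 at 24 months 2 of 84 were as large, with 121 and 678, and the highest set the 3 libraries of 4-5 months in run B against those of run A and 24 months. For S1 at 12 months the real count was 0, and setting the 3 run A libraries of 4-5 months apart called 1011 genes. The splits of CA1 and S1 point to a structure of the libraries by number run. A real count of 0 is reached by every split, 84 of 84 for S1 and 60 of 60 for CA2 at 12 months and 100 of 100 for APP/PS1, so these splits say nothing about chance; the highest others were 5 for CA2 and 2 for APP/PS1. The CA2 count within run B was 587. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the counts and highest others were 2710 and 0 for CA3 at 12 months, 2746 and 1 at 24 months, 432 and 0 and 2696 and 0 for DG, and 2181 and 0 and 1871 and 0 for V1.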

How the results depend on the processing

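The tests without both Rasgrp2 lines, with Sh3bgrl2 or Rasgrp2 lines alone, with length and GC offsets, with library weights, without the S1 libraries of run A, without CA2 replicates 1 and 9 of 4-5 months and without replicate 3 of ECII at 12 months were chosen after the result was seen. Each pair of a result and an alternative was counted once. Counts of genes stayed within 1.5 times of the value reported in 309 pairs and did not in 117. Named genes kept their call and direction in 2779 pairs, were no longer called in 233 and changed sign in 12. Genes not tested under an alternative were left out. Only a chosen part of the 35 lists was followed, where camera had called them at a correlation of 0.01. These lists kept their call in 1846 pairs, were no longer called in 96 and were called in the other direction in 11. The estimated correlation is not among these list pairs. For the changes below the cause was not tested, except where fewer libraries or genes, a fold minimum or its absence bring the change by construction. No paired analysis was possible because the labels number replicates within a group and give no link between libraries of different groups. All alternatives planned were run, but that of APP/PS1 males alone left out no library and so repeated the main fit. Its 1 count and 1 list are among the pairs that stayed the same, and they carry no information. Planted 2-fold changes were recovered at 17.9% in S1 at 12 months and 3% in the APP/PS1 set.

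Pooling the types in 1 fit and adding the number run both moved the age counts. In 1 fit over the wild-type libraries, without the run, the counts were 723 and 2382 for CA1 at 12 and 24 months, 248 and 188 for CA3, 189 for DG at 12 months, 690 and 2385 for S1, and 2828 for V1 at 24 months. With the run as a covariate they were 19 and 204 for ECII, 758 and 0 for CA1, 4 for CA2 at 12 months, 14 and 0 for CA3, 29 and 19 for DG, 319 and 13 for S1, and 547 and 1047 for V1. The effect of run C is then set by 3 CA2 libraries alone, against which all 24-month libraries are measured. In that fit C4b reversed to log2 -0.66 in CA1 and -1.19 in S1 at 24 months, Igf2 to 0.86 in CA1, Pcdhb9 to -0.22 in CA3 and, at 12 months, Atp5mpl to -0.32 in CA3. In ECII at 24 months Gja1 reversed to -0.20, Pros1 to -0.059, Osmr to -0.12, and the medians of cholesterol synthesis to -0.30 and of beta protocadherins to -0.46. Medians of oxidative phosphorylation reversed to -0.15 in ECII, -0.14 in CA1 and -0.23 in CA3 at 12 months and to 0.10 in S1 at 24 months, and those of ribosomal proteins to -0.11 in CA1, -0.15 in CA2 and -0.23 in CA3 at 12 months. In run B alone, at 12 months, the counts were 685 in ECII, 1405 in CA1, 587 in CA2 and 2 in S1. There Il1rapl2 reversed to 0.29 in ECII, and in CA2 oxidative phosphorylation to -0.065 and ribosomal proteins to -0.061. Without the run A libraries of S1 at 4-5 months, 1 gene was called at 12 months and 1538 at 24 months.

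With an adjusted p alone and no fold minimum, identity counts were 6948 for ECII, 6957 for CA1, 6203 for CA2, 4658 for CA3, 2502 for DG, 7287 for S1, 5524 for V1 and 5548 for ECII with CA1, and the lines gave 5638 for ECII and 3478 for CA1. With a fold of at least 1.5, age counts were 960 and 1502 for ECII, 696 and 1905 for CA1, and 1548 and 1432 for CA3 at 12 and 24 months, and 981 for the difference between ECII and other types. With no filter there were 5010 for ECII identity, 943 for DG at 12 months and 2 for S1 at 12 months. With the stricter filter identity counts were 1575 for ECII, 1640 for CA2, 2034 for S1 and 756 for ECII with CA1, the lines gave 1469 for ECII and 561 for CA1, and age gave 694 for DG and 1 for S1 at 12 months and 273 for S1 at 24 months. limma-voom with the line as a block called 1652 for ECII, 1233 for CA1, 1376 for CA2, 1236 for CA3, 679 for DG, 1516 for S1, 2091 for V1 and 535 for ECII with CA1. DESeq2 called 10 for CA2, 1092 for DG and 58 for S1 at 12 months, 845 for S1 at 24 months, 3501 and 3131 for V1, and 255 for APP/PS1. APP/PS1 gave 1 with library size only and 20 with limma-voom and library weights.

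Lines left out also moved counts. Without line 199D5-Rasgrp2 ECII gave 1682 at 12 months, without 344N1-Rasgrp2 1442 and 2853 at 12 and 24 months, without Sh3bgrl2 founder #33 901 and 2079, and without a line covariate 1581 at 12 months. Sh3bgrl2 lines alone gave 1017 and 2859, and Rasgrp2 lines alone 2010 at 24 months. Without the Cck line CA1 gave 795 for identity and 960 and 2077 for age. Without the Rasgrp2 lines Pln reversed to -0.24 in ECII and Cbr2 to -0.041 in ECII with CA1. Length and GC offsets gave 2125 for ECII, 1215 for CA3 and 186 for S1 at 24 months. With an estimated correlation 44 list tests were called. Shared age calls numbered 652 in at least 4 types and 659 at a fold of at least 1.5, and the APP/PS1 overlap was 9 for the 200 genes in each direction. Leaving out 1 library at a time gave 1576 to 2798 for CA3 at 12 months and 1582 to 2827 at 24 months, 80 to 680 for DG at 12 months and 1012 to 2608 at 24 months, 4 to 56 for S1 at 24 months, 928 to 2020 and 682 to 2208 for V1 at 12 and 24 months, and 0 to 1 for APP/PS1. Identity counts kept within 1.5 times of those reported, with 1762 to 2526 for CA3 and 1044 to 1489 for DG.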

Other observations

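Prnp, which encodes the prion protein, was called higher with age in 5 of 6 types at 24 months, by 0.38 ± 0.10 in ECII, 0.45 ± 0.12 in CA1, 0.57 ± 0.11 in CA3, 0.70 ± 0.18 in DG and 0.74 ± 0.14 in V1. The cholecystokinin gene Cck fell at 24 months by 0.82 on the log2 scale in ECII, 0.90 in CA3 and 1.11 in DG. Rpl10a, the gene of the tagged ribosomal protein, fell by 0.86 in ECII, 0.68 in CA1, 0.73 in CA3 and 1.67 in DG. Thy1, a surface protein of mature neurons, fell by 0.83 in ECII and 0.56 in DG. All 24-month libraries have numbers of run C, so age and run cannot be told apart in these changes. In the 3 CA2 libraries of run C labelled 4-5 months Prnp was higher than in the 6 others by 0.455 ± 0.19, not called. The ribosomal proteins had a median of -0.715 there.

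Per library, Prnp ran from 971 to 1920 CPM in the 8 ECII libraries with the APP/PS1 transgenes, and was at 711, 336 and 282 CPM in the 3 without them. In wild-type ECII at 4-5 months it averaged 211 ± 48.9 CPM (n = 17).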
